A study of Mus musculus and Homo sapiens with 22 samples.

How the data were processed

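The series held 22 samples, of which 10 were RNA-seq of N2A or 293T cells and 12 were crosslinking and immunoprecipitation libraries. The latter were not analysed here. The 10 RNA-seq samples had 8 processed files. Per the labels, the shGFP and shnSR100 files each combined 2 runs of different read lengths, so each was used as 1 pooled file with no SD or n. The siRNA files were 2 controls (a and b), 1 U2af65 knockdown (letter a) and 1 Ptbp1 knockdown (letter b). Per the labels' protocols, hairpin cells were selected with 2 ug/mL puromycin, siRNA cells were harvested at 48 hours, and the text attached to both 293T samples describes induction with 1 ug/mL doxycycline for 48 hours. Total RNA was extracted with TRI Reagent and made into Illumina mRNA-Seq libraries by the manufacturer's standard steps, per the labels' protocols. Nothing in the labels says that the control siRNA libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

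The deposited files give, per Ensembl gene, a read count and an RPKM value, scaled by gene length and by total reads, that the authors computed, with no header line. A blank count was read as 0. The RPKM of a gene equalled its read count divided by a length fixed per gene and by the file's total count, as checked from the ratio of the columns. That length, called effective length, is only a few bases for some genes, whose RPKM then rests on a handful of reads. Genes without an RPKM numbered 1114 in the mouse and 354 in the human files. Bowtie, bedtools 2.17.0 and the builds hg19 and mm9 are named per the submitters' processing notes, with no role attached. The counting rule, strand use, annotation version and read filters were not given in the sources used here. Overlapping genes, antisense pairs and genes with close copies (such as Gapdh, Rps27 and Rps27rt) are therefore uncertain.

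Symbols were matched to 20759 of 22667 mouse identifiers. None of the 19847 human identifiers was paired with a symbol, so 293T genes are given by identifier, and gene lists and comparisons across species were not analysed here. Neighbouring genes were taken from the order of genes in a RefSeq annotation of GRCm38.p6, without its coordinates.

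The plan fixed before the data were examined assumed that the files held RPKM only and named limma on log2(RPKM + 1) as the test. The files also hold raw counts, so edgeR's quasi-likelihood test became the main test and limma an alternative. This change was made after the data were seen, when the counts from both tools were known, and the counts from limma are given beside those from edgeR. edgeR 4.0.16 (R 4.3.3, limma 3.58.1) was run on the 4 siRNA libraries with TMM scaling, on 11237 genes with a mean of at least 1 RPKM. The adjusted p is Benjamini-Hochberg, with a threshold of 0.05. The fit has 1 residual degree of freedom, from the control pair, moderated across genes with 8.65 prior degrees of freedom, and its common dispersion was 0.0375. The SE of a log2 fold change is approximate, the fold change divided by the square root of its F statistic. CPM are TMM-scaled.

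Comparisons with 1 file per group were described, not tested. Genes with at least 1 RPKM in one file were counted when log2(RPKM + 1) differed by 1 or more, which understates the change of low genes. Counting intervals are exact binomial at 95%.

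The 25 gene lists were fixed before the data were examined: neuronal splicing regulators, U2 snRNP and 3′ splice site factors, SR proteins, hnRNP genes, pan-neuronal markers, REST-repressed genes, neural progenitor markers, noradrenergic neuroblastoma regulators, p53 targets, ATF4 response, unfolded protein response, G2 and mitosis, DNA replication, intronless genes, immediate early genes, cholesterol synthesis, interferon-induced genes, ribosomal proteins, respiratory chain subunits, glycolysis and hypoxia, cytoskeleton and cell contact, and glial, immune, fibroblast, and endothelial and epithelial markers. The 21 lists with at least 5 tested members went through limma's camera with a preset correlation of 0.01, adjusted over the 42 tests of both knockdowns, and again with an estimated correlation. With an estimated correlation, both the estimate and the test rest on the 1 residual degree of freedom. That version could hardly call any list, so a call lost there does not decide for or against a list. The preset correlation treats the members of a list as nearly independent. A call made with it therefore does not separate a knockdown from a difference between single libraries. Counts adjusted over the list alone use Benjamini-Hochberg within 1 list, with no correction over the lists or knockdowns. The members of a list share the same libraries, so these counts are not independent. For the nSR100 knockdown a list's median was placed among 10000 random lists of the same size matched on expression in 20 bins.

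Genes were named by a rule fixed in advance: the targeted genes with Ptbp2, Rest and Dlg4; per comparison the 12 largest increases and 12 largest decreases, without genes lacking a symbol, predicted genes, pseudogenes, small RNAs and immunoglobulin or T cell receptor segments; and per list up to 4 measured members with the largest differences. For siRNA these were genes past the edgeR threshold and of the same sign against each control, ranked by the smaller difference. The rule as fixed named the limma threshold, and edgeR's replaced it when the main test was changed. This left fewer genes to name after Ptbp1 knockdown. For single files they had at least 5 RPKM in one file. In 293T, 2 identifiers per direction are given. In the closing section, Bnip3, Slc2a1 and Pfkm were chosen after their values were seen.

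The test was run on simulated data in 10 simulations of the U2af65 comparison over 11237 genes with 200 changed. It recovered 31.5% of 2-fold and 93.6% of 4-fold changes, with a mean of 7.50 false calls. Simulated genes were independent, both controls shared the same mean, and the knockdown library varied as the fit assumes. The real control libraries differed in whole gene lists, so these rates may not carry over. DESeq2 1.42.0 and edgeR's own filter on counts were among the alternatives added after the data were seen. The other alternatives covered the filter, the pseudocount, scaling, quantile normalization, trended and robust variance, shGFP as a further control, and leaving out each control. The shGFP file is from stable, puromycin-selected hairpin cells, unlike the siRNA controls. Fits that use it as a control therefore count differences between hairpin and siRNA cells as spread.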

Results

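RNA-seq was used on 2 cell lines to ask how 3 proteins that act on splice site choice shape the transcriptome. N2A is a mouse neuroblastoma line and 293T a human embryonic kidney line. nSR100, encoded by Srrm4, is a neuronal SR-related splicing factor. Ptbp1 is a polypyrimidine tract binding protein that represses neuronal exons, and U2af65, encoded by U2af2, binds the polypyrimidine tract at the 3′ splice site. The study's stated interest was alternative splicing. The values used here are reads per gene, so they describe gene expression and not exon inclusion. The N2A cells carried a stable hairpin against GFP or nSR100, or were harvested 48 hours after transfection of a control siRNA pool or of a pool against U2af65 or Ptbp1. The 293T cells were a control and a line made to express nSR100. The control siRNA group had 2 libraries, a and b. Every other group had 1 file, and each hairpin file combined 2 sequencing runs. Reads in genes totalled 60220620 for shGFP, 73600542 for shnSR100, 63952996 and 77138004 for controls a and b, 68416863 for siU2af65 and 69957246 for siPtbp1. The 293T files held 111941702 reads for the control and 110652253 for nSR100.

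Each targeted gene was lowest in its own knockdown among the N2A files. Ptbp1 stood at 468 ± 70.3 CPM in the control siRNA libraries (SD, n = 2) and 25.9 CPM in siPtbp1, and it fell by 4.18 on the log2 scale (SE 0.32, edgeR adjusted p = 0.00242). U2af2 stood at 241 ± 26.6 CPM in the controls (SD, n = 2) and 37.8 CPM in siU2af65, and it fell by 2.67 (SE 0.26, edgeR adjusted p = 0.00468). With shGFP added to the controls both calls were lost in edgeR while the differences stayed close, at -4.07 for Ptbp1 (adjusted p = 0.999) and -2.56 for U2af2 (adjusted p = 0.389). Over all alternatives the adjusted p ran from 2.25e-79 to 1.000 for Ptbp1 and from 2.97e-30 to 1.000 for U2af2. Srrm4 had 1365 reads in shnSR100 and 5203 in shGFP, and its RPKM was 21.5% of the control (95% counting interval 20.2 to 22.8%, exact binomial). Srrm4 itself varied among the siRNA libraries, at 36.1 CPM in control a, 61.3 in control b, 85.5 in siU2af65 and 33.2 in siPtbp1. In 293T cells the largest increase was that of ENSG00000139767, with 65917 reads under nSR100 and 9 in the control. The files and tables used here do not pair human identifiers with symbols, so no targeted gene was looked up by name in 293T.

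**Figure D1:**
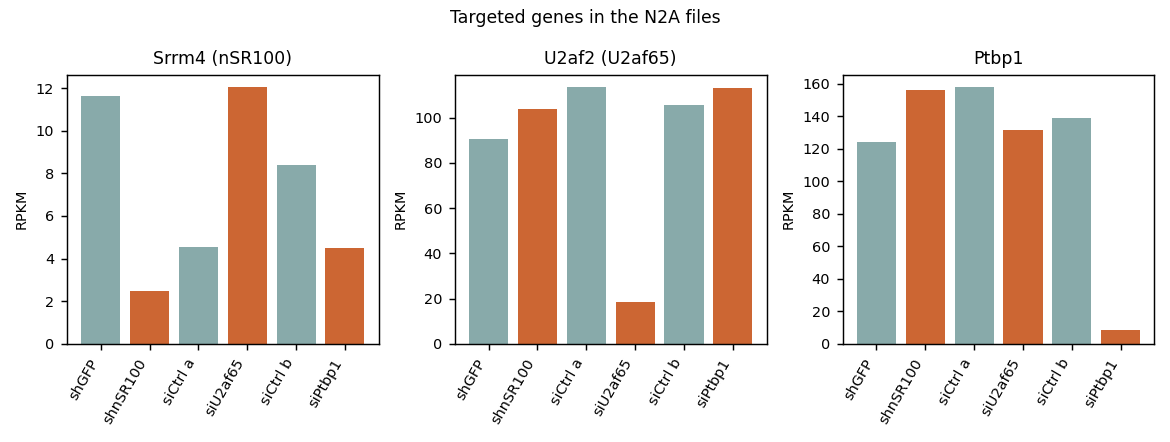
RPKM of Srrm4, U2af2 and Ptbp1 (vertical axes, from 0) in each of the 6 N2A files (horizontal axes), 1 bar per file, with control files in grey and knockdown files in orange. Each targeted gene was lowest in its own knockdown, at 18.4 RPKM for U2af2, 8.53 RPKM for Ptbp1 and 21.5% of shGFP for Srrm4.

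Ptbp2, Rest and Dlg4 were fixed in advance as genes tied to these regulators. Ptbp2, the neuronal paralog of Ptbp1, stood at 157 ± 33.8 CPM in the controls (SD, n = 2) and 260 CPM in siPtbp1, a log2 difference of 0.72 (SE 0.24) that did not pass the test (edgeR adjusted p = 0.961). Dlg4, which encodes the postsynaptic protein PSD-95, fell by 1.14 after U2af65 knockdown (SE 0.27, edgeR adjusted p = 0.0449, and 7.13e-05 to 1.000 over the alternatives) and had a log2 difference of 0.24 after Ptbp1 knockdown (SE 0.26, adjusted p = 0.999). Rest, the repressor of neuronal genes, had a log2 difference of -0.51 after U2af65 knockdown (SE 0.25, adjusted p = 0.259) and 0.04 after Ptbp1 knockdown (SE 0.25, adjusted p = 0.999). Between the hairpin files, Rest was 10.8 RPKM in shGFP and 12.6 in shnSR100, Dlg4 was 60.3 and 47.9, and Ptbp2 was 31.5 and 28.2.

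After U2af65 knockdown, genes of mitosis and of sterol synthesis had negative differences in every measured member. All 29 measured G2 and mitosis genes had negative log2 differences, with a median of -0.97, and 15 of them fell. The list passed the camera test with its preset correlation (adjusted p = 1.89e-20), and the call was lost when the correlation was estimated (adjusted p = 0.967 with an estimated correlation). Ccna2, which encodes cyclin A2, fell by 1.75 (SE 0.25, edgeR adjusted p = 0.0114). Nusap1, a spindle protein gene, had a difference of -1.61 (SE 0.23), and the mitotic kinase genes Aurka and Aurkb had differences of -1.56 (SE 0.25) and -1.55 (SE 0.27), all past the threshold. A total of 28 of the 29 fell when adjusted over the list alone. This list also differed between the controls, with a median of -0.19 for control b minus control a, at percentile 1.68 of matched random lists. Its median was -1.07 for siU2af65 against control a. The test with an estimated correlation rests on 1 residual degree of freedom. A camera call lost with it does not decide for or against this or any later list. Nor does a call with the preset correlation separate a knockdown from a difference between libraries. Such a call was also made for glycolysis and hypoxia genes after Ptbp1 knockdown, whose median differed by -1.41 between the controls. Of 33 DNA replication genes 4 fell and 1 rose, with a median of -0.25 (camera adjusted p = 0.00170, and adjusted p = 0.967 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, had a difference of -1.52 (SE 0.23), the replication fork factor Cdc45 one of -1.38 (SE 0.24) and the cyclin gene Ccne1 one of -1.34 (SE 0.24), while Tyms, the thymidylate synthase gene, rose by 1.00 (SE 0.24). In this list 5 fell and 1 rose when adjusted over the list alone. Against control a alone the list's median was -0.27, at percentile 4.11 of matched random lists and so inside their central 95%.

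Cholesterol synthesis genes had negative differences in all 23 measured members after U2af65 knockdown, with a median of -0.74, and 5 fell (camera adjusted p = 1.18e-09, and adjusted p = 0.967 with an estimated correlation). The sterol reductase gene Tm7sf2 went from 28.2 ± 6.33 CPM in the controls (SD, n = 2) to 2.00 CPM, and it fell by 3.81 (SE 0.40, edgeR adjusted p = 0.00493). Pmvk, a mevalonate pathway kinase, had a difference of -1.32 (SE 0.23, adjusted p = 0.0175). In this list 13 fell when adjusted over the list alone. The list's median was 0.11 for control b minus control a, at percentile 99.25 of matched random lists, and -0.66 for siU2af65 against control a. Of 27 cytoskeleton and cell contact genes 4 fell (median -0.51, camera adjusted p = 4.20e-05, and adjusted p = 0.967 with an estimated correlation). Myl9 had a difference of -2.89 (SE 0.67), Tpm3 one of -2.11 (SE 0.48) and Cnn2 one of -2.02 (SE 0.34), and 7 fell when adjusted over the list alone. This list also differed between the controls, with a median of -0.28 for control b minus control a. Its median was -0.65 for siU2af65 against control a. Of 21 genes of the unfolded protein response of the endoplasmic reticulum 2 fell, over all genes and adjusted over the list alone (median -0.51, camera adjusted p = 0.00953, and adjusted p = 0.967 with an estimated correlation). Against control a alone its median was -0.39, at percentile 3.07 and also inside the central 95%. Between the controls its median was 0.19 for control b minus control a, at percentile 99.97. The 2 calls were Sdf2l1, at -1.34 (SE 0.25), and the disulfide isomerase gene Pdia4, at -1.20 (SE 0.25).

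Of 31 genes of the ATF4 and amino acid response 5 rose and 0 fell after U2af65 knockdown, and 22 had positive and 9 negative differences, with a median of 0.47 (camera adjusted p = 1.11e-04, and adjusted p = 0.967 with an estimated correlation). Ppp1r15a, which encodes the phosphatase subunit GADD34, rose by 1.88 (SE 0.21), the pseudokinase gene Trib3 by 1.63 (SE 0.26) and Stc2 by 1.41 (SE 0.30). In this list 7 rose when adjusted over the list alone. This list also differed between the controls, with a median of 0.37 for control b minus control a, and its median was 0.52 for siU2af65 against control a.

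**Figure D2:**
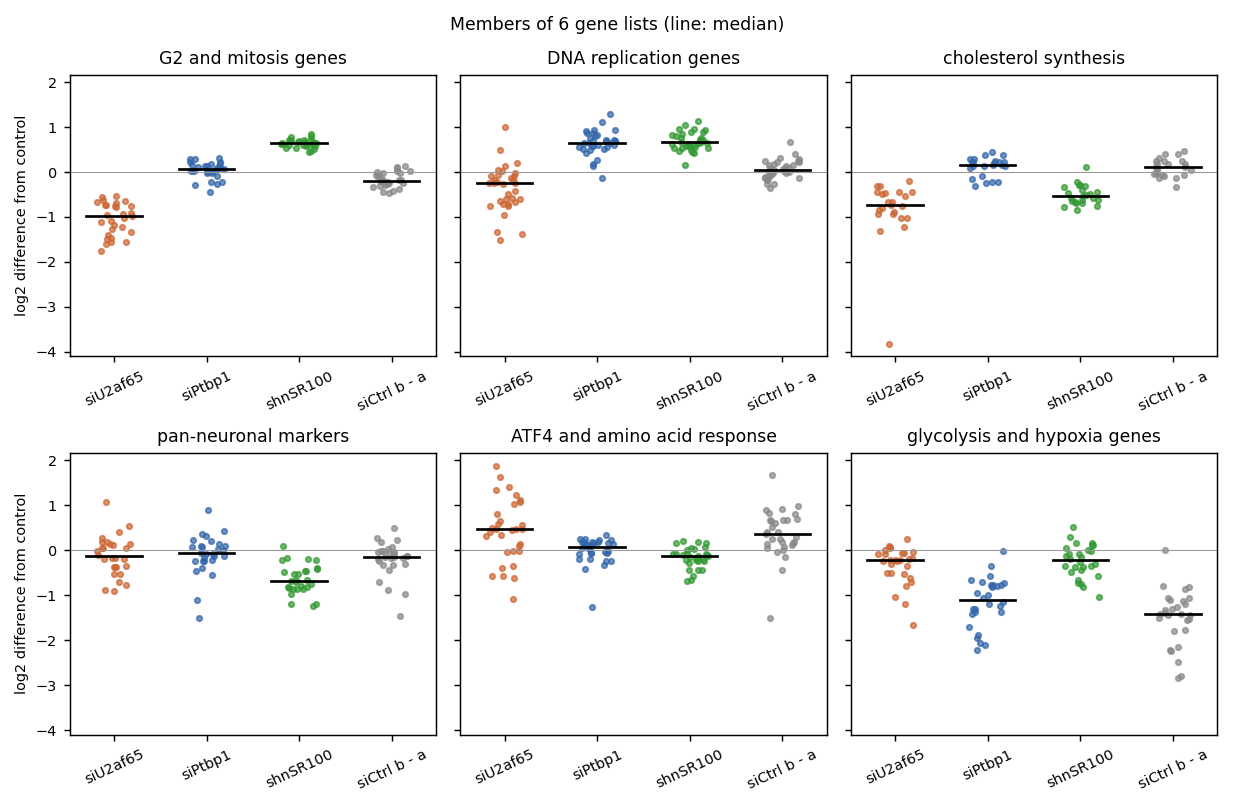
Log2 difference (vertical axis) of each measured member (points) of 6 gene lists (panels) after U2af65, Ptbp1 and nSR100 knockdown and between the control siRNA libraries (horizontal axis), with the list's median as a line. The siRNA knockdowns are edgeR estimates against both controls, nSR100 is a difference of log2(RPKM + 1) and the control pair a difference of log2 CPM. G2 and mitosis genes had medians of -0.97 in siU2af65 and 0.64 in shnSR100, and glycolysis and hypoxia genes had a median of -1.41 between the controls.

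Splicing factor genes were called singly after U2af65 knockdown. Hnrnpd fell by 1.97 (SE 0.26, edgeR adjusted p = 0.00848) and Hnrnph3 had a difference of -1.13 (SE 0.22, adjusted p = 0.0263), and these were the 2 of 27 hnRNP genes that fell, against 3 adjusted over the list alone. The U2 snRNP gene Snrpa1 had a difference of -0.89 (SE 0.22, adjusted p = 0.0479), so that with U2af2 itself 2 of 24 U2 snRNP and 3′ splice site factors fell, and 2 adjusted over the list alone. Srsf6 rose by 0.95 (SE 0.22), 1 of 22 SR protein genes, and the neuronal regulator Celf6 fell by 1.24 (SE 0.29), 1 of 14 neuronal splicing regulators, with 1 in each list adjusted over the list alone. These 4 lists did not pass the camera test, with adjusted p of 0.0548, 0.702, 0.879 and 0.254 in that order. The U2 snRNP list had a median of 0.05 and a mean of -0.08. Over all 11237 tested genes 5.24% were called, and whether these 4 lists held more calls than that share was not tested.

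Lists of neuronal identity genes did not pass the camera test after U2af65 knockdown. The neurofilament gene Nefh rose by 1.07 (SE 0.21), 1 of 28 pan-neuronal markers, and the sodium channel gene Scn3b fell by 1.08 (SE 0.23), 1 of 25 REST-repressed genes. Adjusted over the list alone, 1 pan-neuronal marker rose and 2 fell, and 4 REST-repressed genes fell. Of 16 noradrenergic neuroblastoma regulators 1 rose and 2 fell, and 2 rose and 5 fell adjusted over the list alone. The transcription factor gene Tfap2b fell by 2.24 (SE 0.46), and Isl1 had a difference of -1.70 (SE 0.30, edgeR adjusted p = 0.0179). Prom1 fell by 1.46 (SE 0.34), 1 of 11 neural progenitor markers, and 1 adjusted over the list alone. The test first planned, limma on log2(RPKM + 1), did not call Scn3b, Tfap2b or Prom1. Scn3b was also lost in edgeR with a mean of at least 5 RPKM. The camera adjusted p was 0.583, 0.0942, 0.0942 and 0.736 for these 4 lists.

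Other lists held few calls after U2af65 knockdown. Egr1 fell by 1.94 (SE 0.45), 1 of 3 calls among 23 immediate early genes (camera adjusted p = 0.0584), of which 3 rose and 6 fell adjusted over the list alone. Egr1 was 417 CPM in control a and 178 in control b, and its call was lost with robust edgeR and with a mean of at least 5 RPKM. Among 18 p53 targets Ei24 fell by 1.66 (SE 0.28), among 14 intronless genes Sox12 rose by 0.88 (SE 0.22), and among 62 respiratory chain subunits Sdhc fell by 0.96 (SE 0.21), with camera adjusted p of 0.740, 0.616 and 0.493. Adjusted over the list alone, 1 p53 target rose and 2 fell, 2 intronless genes rose, and 0 respiratory chain subunits were called. No member was called by edgeR over all genes among 16 interferon-induced genes, 75 cytoplasmic ribosomal proteins and 28 glycolysis and hypoxia genes (camera adjusted p = 0.509, 0.696 and 0.493). Adjusted over the list alone, 1 interferon-induced gene rose and 2 fell, and 0 were called in the other lists.

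Over all 11237 tested genes, 205 rose and 384 fell after U2af65 knockdown (edgeR, adjusted p threshold 0.05). Of the genes that rose 28 were under 1 RPKM in the controls, against 0 of those that fell, since the filter on mean RPKM includes the knockdown library and so lets in genes that are low in the controls when they are higher in it. The named increases were led by Fam186b, which rose by 4.95 (SE 0.55) from 0.576 ± 0.341 CPM in the controls (SD, n = 2) to 18.1 CPM, Tmem179 by 4.73 (SE 0.47) and the sulfotransferase gene Chst15 by 4.69 (SE 0.59). The others, Bcl2l15, Avil, Als2cl, Vpreb3, Slamf9, Cox6a2, Akr1b7, Car6 and Dusp26, rose by 2.63 to 3.55. Among the named decreases, the myosin light chain gene Myl12b had a difference of -3.39 (SE 0.34), Gpr22 one of -3.44 (SE 0.40), Acap1 one of -3.16 (SE 0.45) and Idh2, the mitochondrial isocitrate dehydrogenase gene, one of -2.80 (SE 0.26). Lgals4, Hist1h1b, S100a1, Psrc1, the DNA glycosylase gene Neil3 and the DNA helicase gene Pif1 had differences of -3.43 to -2.40. Of the immune markers, Tyrobp rose from 0.151 and 0.357 CPM in the controls to 1.68 CPM in edgeR, a call that DESeq2 did not make. Coro1a had a difference of -1.70 (SE 0.36, edgeR adjusted p = 0.0329). The fibroblast marker S100a4 had a difference of -1.17 (adjusted p = 0.171) and the endothelial marker Pecam1 one of 0.82 (adjusted p = 0.134).

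The spread in these tests came from the control pair alone, with 1 residual degree of freedom, and the lone knockdown library was assumed to vary like the controls. In the fits with shGFP as a control, the spread also took in the difference between stable hairpin cells and siRNA cells. Calls lost in those fits therefore do not measure how well the knockdown differences hold against siRNA controls. The U2af65 counts were 655 and 630 with the test first planned, limma on log2(RPKM + 1), 581 and 581 in edgeR with library totals in place of TMM, and 0 and 0 in edgeR with shGFP added to the controls or put in place of control a or of control b.

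After Ptbp1 knockdown few single genes were called. At 2-fold or more on the log2(RPKM + 1) scale, siPtbp1 differed from control b at 69 genes and from control a at 263. The controls differed from each other at 194. The control pair that gave the test its spread thus lay further apart than siPtbp1 and control b. The number of calls therefore does not measure the size of the response. Besides Ptbp1, the actin cross-linking protein gene Flna fell by 2.87 (SE 0.32), from 773 ± 28.6 CPM in the controls (SD, n = 2) to 106 CPM, and the extracellular matrix gene Fbln2 had a difference of -2.41 (SE 0.27), from 313 ± 32.9 to 59.2 CPM (edgeR adjusted p = 0.0190 for each). In edgeR 3 of 11237 genes fell and 0 rose. At an unadjusted p under 0.05, edgeR had 173 genes higher and 308 lower, in all 481 where chance alone gives 562. At an adjusted p under 0.05, limma on log2(RPKM + 1), the test first planned, called 29 higher and 70 lower, and DESeq2 called 1 higher and 19 lower. With shGFP added to the controls, or in place of control a or b, edgeR called 0 genes. No gene was called either with limma after quantile normalization or with edgeR without a trend, both without shGFP.

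DNA replication genes were higher as a group after Ptbp1 knockdown. Of 33 members 32 had positive differences, with a median of 0.65 (camera adjusted p = 5.73e-37), and the call was lost when the correlation was estimated (adjusted p = 0.967 with an estimated correlation). The median was 0.64 against control b alone and 0.05 between the controls. None of the 33 was called by edgeR over all genes tested, and 24 rose when adjusted over the list alone. The licensing factor gene Cdc6 had a log2 difference of 1.28 (SE 0.32, edgeR adjusted p = 0.630), the cyclin E genes Ccne2 and Ccne1 differences of 1.12 (SE 0.22, adjusted p = 0.417) and 0.93 (SE 0.22, adjusted p = 0.593), and the helicase subunit gene Mcm4 one of 0.93 (SE 0.20, adjusted p = 0.477).

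Cytoskeleton and cell contact genes had negative differences after Ptbp1 knockdown in 23 of 27 members, with a median of -0.52 (camera adjusted p = 4.83e-19, and adjusted p = 0.967 with an estimated correlation). The median was -0.26 against control b alone and -0.28 between the controls. Flna was the 1 call, and adjusted over the list alone 7 fell. Cnn2 had a log2 difference of -1.92 (SE 0.34, edgeR adjusted p = 0.336). Of 16 noradrenergic regulators 15 had negative differences, with a median of -0.36 (camera adjusted p = 3.57e-06, and adjusted p = 0.967 with an estimated correlation). For this list the median was -0.27 against control b alone and -0.24 between the controls. Ddc, which encodes an enzyme of dopamine synthesis, had a difference of -1.57 (SE 0.45, adjusted p = 0.821). Of 21 unfolded protein response genes 19 had positive differences, with a median of 0.28 (camera adjusted p = 5.61e-04, and adjusted p = 0.967 with an estimated correlation). For this list the median was 0.15 against control b alone and 0.19 between the controls. The chaperone gene Hspa5 had a difference of 0.70 (SE 0.36, adjusted p = 0.999). In both of these lists 0 members were called, over all genes and adjusted over the list alone.

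Glycolysis and hypoxia genes had negative differences in 28 of 28 members after Ptbp1 knockdown, with a median of -1.10 (camera adjusted p = 5.02e-20, and adjusted p = 0.967 with an estimated correlation), and 0 members were called, over all genes and adjusted over the list alone. A difference also lay between the controls, with a median of -1.41 for control b minus control a, and the median was -0.18 for siPtbp1 against control b. Adm, which encodes adrenomedullin, was 130 CPM in control a, 18.2 in control b and 15.9 in siPtbp1. The remaining lists did not pass for Ptbp1. These tests used both controls, which lay apart in whole lists, so not passing does not show that a list was unchanged. Camera adjusted p was 0.731 for neuronal splicing regulators, 0.666 for U2 snRNP factors, 0.616 for SR proteins and 0.104 for hnRNP genes, in which Ptbp1 was the 1 call. It was 0.408 for pan-neuronal, 0.509 for REST-repressed and 0.554 for progenitor genes, 0.235 for p53 targets, 0.733 for ATF4, 0.583 for G2 and mitosis, 0.552 for intronless and 0.980 for immediate early genes. It was 0.104 for cholesterol synthesis, 0.472 for interferon-induced genes, 0.583 for ribosomal proteins and 0.0780 for respiratory chain subunits. Adjusted over the list alone, 1 U2 snRNP factor and 1 pan-neuronal marker fell, and 0 genes of the others were called apart from Ptbp1. Median and mean differed in sign for the U2 snRNP, ATF4 and immediate early lists. Against control b alone, immediate early, progenitor and ribosomal protein genes had medians of 0.29, 0.26 and 0.17. Respiratory chain subunits and G2 and mitosis genes had medians of 0.15 each. These lay at percentile 99.56 or above of matched random lists, and ATF4 (median -0.10) at percentile 1.19. The other lists that did not pass lay at percentiles 2.55 to 93.34. Such places do not separate a knockdown from a difference between libraries.

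In the nSR100 knockdown, neuronal genes were lower and proliferation genes higher than in shGFP. Of 28 pan-neuronal markers 27 were lower, with a median log2(RPKM + 1) difference of -0.68. The secretory granule gene Chga was 164 RPKM in shGFP and 68.6 in shnSR100, the synaptic vesicle gene Syn1 21.5 and 8.83, the SNARE gene Snap25 102 and 44.5, and Stmn2 287 and 146. REST-repressed genes were lower in 23 of 25 members, with a median of -0.66. Neuronal splicing regulators were lower in 12 of 14, with a median of -0.77. Srrm4, the targeted gene, belongs to both of these lists, and without it 22 of 24 REST-repressed genes (median -0.65) and 11 of 13 neuronal splicing regulators (median -0.71) were lower. The latter included Celf3 at 67.3 and 27.3 RPKM, Celf6 at 14.2 and 6.29, and Srrm3, a paralog of Srrm4, at 14.6 and 6.61. All 33 DNA replication genes were higher in shnSR100, with a median of 0.67, and all 29 G2 and mitosis genes, with a median of 0.64. Tyms was 9.26 RPKM in shGFP and 21.5 in shnSR100, Cdc6 6.34 and 14.1, Birc5 62.7 and 112.8, and Aurkb 17.3 and 30.4.

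Between the control siRNA libraries, which belong to 1 group, 11 of 21 lists lay outside the central 95% of matched random lists, with medians of -1.41 for glycolysis and hypoxia genes, -0.45 for immediate early genes, -0.37 for ribosomal proteins and 0.37 for the ATF4 response. A list's place among random lists therefore does not separate a knockdown from a difference between libraries of 1 group. For nSR100, the medians of the 3 neuronal lists lay at percentile 0 and those of the cell cycle lists at percentile 100. Cholesterol synthesis genes were lower in 22 of 23 members, with a median of -0.53 and a percentile of 0, as in Hsd17b7 at 16.2 RPKM in shGFP and 8.52 in shnSR100. Immediate early genes had a median of -0.41 (percentile 0), with Egr1 at 39.4 and 15.2 RPKM and Dusp6, a MAP kinase phosphatase gene, at 136 and 56.8. Noradrenergic regulators had a median of -0.31 (percentile 0), with the oncogene Mycn at 26.9 RPKM in shGFP and 11.3 in shnSR100. Also on the low side were glycolysis and hypoxia genes (median -0.22, percentile 0), intronless genes (-0.27, percentile 0.03), p53 targets (-0.26, percentile 0.01), the ATF4 response (-0.13, percentile 0.01) and ribosomal proteins (-0.03, percentile 1.88). Higher were hnRNP genes (0.18, percentile 99.9), the unfolded protein response (0.25, percentile 99.99) and respiratory chain subunits (0.11, percentile 98.9). Within the range of random lists were U2 snRNP factors (0.12, percentile 93.8), SR proteins (0.11, percentile 85.3), neural progenitor markers (0.16, percentile 94.8), interferon-induced genes (0.10, percentile 89.2) and cytoskeleton genes (0.07, percentile 75.1). Of other cell types' markers, 5 fibroblast genes had a median of -0.19 (percentile 6.02), 4 glial genes one of 0.08, 2 endothelial and epithelial genes one of -0.02, and the 1 measured immune gene, Coro1a, a difference of -0.50.

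At 2-fold or more on the log2(RPKM + 1) scale, 36 genes were higher and 73 lower in shnSR100 among 11877 genes. Among the named genes, the matrix gene Col4a1 was 50.8 RPKM in shGFP and 130.5 in shnSR100, the cytokine gene Il6 6.50 and 23.5, Ahsg 3.61 and 14.7, Gpnmb 1.32 and 6.63, and the metallothionein gene Mt1 2.94 and 11.3. Prr9, Kif1c, Nnat, the apoptosis gene Bak1 and the cell cycle repressor gene E2f7 were higher by 1.16 to 1.37. On the other side, Serpinf1 was 23.8 RPKM in shGFP and 5.39 in shnSR100, the acetylcholinesterase gene Ache 42.4 and 14.4, the AMPA receptor auxiliary subunit gene Cacng3 33.6 and 11.6, and Galnt2 77.1 and 28.4. Tmem145, Car6, Egr1 and Elovl4 were lower by differences of -1.47 to -1.28. Mthfs, Mef2b, Rps27, Rps27rt and Zfp986 met the naming rule on 7 reads or fewer in either file, over effective lengths of 2 to 16 bases, and no direction is given for them. Requiring 10 reads in 1 file left 21 higher and 64 lower. There was 1 file per group, so these differences have no replicate check. The control siRNA libraries, both of 1 group, differed by 2-fold or more at 194 of 11350 genes.

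In 293T cells 560 genes were higher and 740 lower with nSR100 at 2-fold or more among 12702 genes, again with 1 library per group. The labels describe the same doxycycline induction for both, and whether the control received the drug is uncertain. ENSG00000139767 was 71.1 RPKM with nSR100 and 0.00959 in the control, and ENSG00000099399 was 19.2 and 0.276 RPKM, from 3240 and 47 reads. ENSG00000051523 was 0.212 RPKM with nSR100 and 83.5 in the control, from 15 and 5962 reads. ENSG00000121390 had 0 reads with nSR100 and 8994 in the control, which is at least 2963-fold lower with the floor set at 3 counts per library. Intervals and floors cover counting error only.

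Responses to the 3 knockdowns were compared across 11077 genes, each against a control library of its own. The U2af65 and Ptbp1 differences correlated at Pearson r = -0.11 (Spearman -0.14), U2af65 and nSR100 at 0.04 (0.05), and Ptbp1 and nSR100 at 0.14 (0.18). With the controls of the other letter, Pearson r was -0.0663 for U2af65 and Ptbp1 and 0.0199 for U2af65 and nSR100, and with a pseudocount of 0.1 RPKM it was 0.0740 for Ptbp1 and nSR100. List medians were taken against the control of the same letter, or shGFP for nSR100. Those for siRNA are of TMM-scaled log2 CPM, while those for nSR100, like the correlations, are of log2(RPKM + 1) without TMM. DNA replication genes had medians of 0.64 for Ptbp1, 0.67 for nSR100 and -0.27 for U2af65. Cholesterol synthesis genes had medians of -0.66 for U2af65, -0.53 for nSR100 and 0.11 for Ptbp1. The siRNA list calls for these groups were lost when the correlation was estimated (adjusted p = 0.967 with an estimated correlation). The differences between knockdowns were not tested, and genes are not independent replicates.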

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

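Alternatives added after the data were seen were DESeq2, library totals without TMM, shGFP in place of 1 control, edgeR's own filter on counts, and a minimum of 10 reads. The planned test was limma on log2(RPKM + 1), and edgeR replaced it after both results were seen. No paired analysis was possible because the letters a and b as a block leave no residual degrees of freedom, and runs 1 and 2 of the hairpin samples were combined into 1 file each. Counts after U2af65 knockdown (205 rose, 384 fell) and Ptbp1 knockdown (0 and 3) depended on how the spread was estimated, on the filter and on the scaling. Of 205 and 384 genes, all 205 and 384 were also called with median-ratio scaling, 201 and 384 with DESeq2, and 199 and 347 with limma on log2(RPKM + 1).

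In the order U2af65 higher, U2af65 lower, Ptbp1 higher, Ptbp1 lower, the calls were 655, 630, 29 and 70 with limma on log2(RPKM + 1), 617, 644, 30 and 76 with a pseudocount of 0.1, and 708, 973, 9 and 90 with no filter on low values. They were 74, 183, 0 and 1 with a mean of at least 5 RPKM, 339, 706, 1 and 19 with DESeq2, 581, 581, 14 and 72 with library totals alone, and 438, 648, 0 and 3 with edgeR's own filter, which tested 14028 genes. They were 0, 0, 0 and 0 with limma after quantile normalization, with edgeR without a trend, with shGFP added to the controls, and with shGFP in place, without control replicate a or b. In these fits U2af2 kept log2 differences of -2.57, -2.67, -2.56, -2.41 and -2.55, with adjusted p from 0.0778 to 1.000. The cause was not tested. In the fits with shGFP, which is from stable hairpin cells, the difference between hairpin and siRNA cells entered the spread. Median-ratio scaling and robust edgeR kept all 4 counts within 1.5 times. For the 62 called siRNA genes that the naming rule gave, 516 comparisons with an alternative kept the call, 334 lost it and 0 turned the direction. All 62 calls were lost in each of the 5 fits that called 0 genes. With a mean of at least 5 RPKM 14 were lost, Dlg4 among them (edgeR adjusted p = 0.0710). Robust edgeR lost 3, namely Snrpa1, Stc2 and Egr1. Each limma fit without quantile normalization lost 3, namely Scn3b, Prom1 and Tfap2b, and DESeq2 lost 1, Tyrobp.

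Without a test, 450 genes were at least 2-fold higher and 309 lower in siU2af65 against the mean of both controls, and 22 and 68 in siPtbp1. Leaving out each control gave 292 to 821 and 334 to 376 for siU2af65, and 22 to 88 and 47 to 175 for siPtbp1; the higher counts for siU2af65 (821) and siPtbp1 (88 and 175) were against control a alone. A pseudocount of 0.1 RPKM gave 93 higher and 154 lower for shnSR100, 1168 lower for 293T and 505 between the controls (main values 36, 73, 740 and 194). A 1.5-fold threshold gave 368 and 438, 1860 and 1937, and 1252. A minimum of 10 reads gave 21 higher for shnSR100. Median-ratio scaling moved the control pair by -0.14 (log2).

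Of 11 list calls in the siRNA knockdowns, 0 remained with an estimated correlation. With a pseudocount of 0.1 or with quantile normalization, limma made 12 in each case. Against the control of the same letter, 19 of the 42 pairs of list and knockdown lay outside the central 95% of random lists. In the nSR100 knockdown 16 lists lay outside, and 15 to 17 under the alternatives. The siRNA list test with an estimated correlation rests on 1 residual degree of freedom, so its 0 calls do not decide for or against a list. The correlation of U2af65 and Ptbp1 responses was -0.0935 at 5 RPKM and -0.0663 with controls of the other letter, that of U2af65 and nSR100 0.0199 with the other control, and that of Ptbp1 and nSR100 0.0740 with a pseudocount of 0.1. The cause was not tested. Total reads ran from 60220620 to 111941702 per file, and depth limits mainly genes with few reads, of which 15 higher and 9 lower in shnSR100 had under 10.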

Other observations

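Of the tests below, those of neighbouring genes and of length-matched lists were fixed before their results were seen. The tests of library scaling, of the letters a and b, of the level of control a, and of the length of genes that rose were chosen after the result was seen.

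Among the 21 tested lists, the control siRNA libraries differed most in genes of the hypoxic response and glycolysis. Of 28 members 27 were lower in control b than in control a. Adm was 130 CPM in control a and 18.2 in control b, the hypoxia-induced gene Ankrd37 148 and 21.4, the mitophagy receptor gene Bnip3 840 and 181, the kinase gene Pdk1 54.7 and 9.79, and the glucose transporter gene Slc2a1 381 and 85.3. Pfkm was the exception, at 133 and 135 CPM. Median RPKM over the list was 172 in control a, 105 in siU2af65, 83.8 in control b, 66.2 in siPtbp1, 62.0 in shGFP and 54.6 in shnSR100. Cytoplasmic ribosomal proteins had a median log2 difference of -0.37 between controls b and a, immediate early genes -0.45 and the ATF4 response 0.37.

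A scaling difference between the controls is argued against, since the list's median lay at percentile 0 of 10000 matched random lists. A batch marked by the letters a and b is a candidate explanation: the siU2af65 library, also of letter a, lay above the siPtbp1 library of letter b by a median of 0.82, in 25 of 28 members. Yet siU2af65 lay between the controls, at a median of 0.67 above control b and -0.70 against control a, and letter and knockdown cannot be separated by the design. Against control b alone, the median for siPtbp1 was -0.18 in place of -1.10, so the list's lower level after Ptbp1 knockdown may come largely from control a. Culture density or oxygen was not tested.

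For the 205 genes that rose after U2af65 knockdown, one hypothesis was that reads running on from an expressed neighbouring gene lifted them. It found no support: the higher expressed neighbour had a median log2(RPKM + 1) of 4.22 over 200 of the 205 genes, at percentile 28.9 of matched unchanged genes. Neighbours were taken by order alone, without strand or distance, and a median can miss a part of the genes. The test therefore does not exclude such reads. Effective length gave a mixed answer. Genes that rose had a median of 2909 bases, at percentile 99.8 of matched sets, while genes that fell, at 2867 bases, lay at percentile 19.0, so a length effect stays open and may add to the increases. The loss of U2af65 itself is the biological explanation and was not tested apart from these.

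The opposite movement of cell cycle and neuronal genes after nSR100 knockdown was weighed against scaling and gene length. Median-ratio scaling shifted all genes by -0.0365 (log2), while the medians of the pan-neuronal, REST-repressed, G2 and mitosis, and DNA replication lists were 0.64 or more in size and of both signs, which argues against scaling. All 4 of these 4 lists lay outside the central 95% of random lists matched on effective length as well as expression, which argues against length. Between the control siRNA libraries the same lists had medians of -0.14, -0.14, -0.19 and 0.05. With 1 file per group, a difference in growth state between the stable populations cannot be separated from nSR100 loss and may account for the pattern.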
